A study of Mus musculus with 12 samples.

How the data were processed

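The study profiled chromatin of the adult wild-type mouse cerebral cortex in 12 libraries, each the only member of its group. Per the labels, 8 libraries were made by CUT&RUN, in which an antibody directs a nuclease to cut out bound chromatin, with antibodies to MECP2 or H3 or with control IgG. Another 2 were made by CUT&Tag, in which the antibody directs a transposase, with antibodies to the C-terminus or the N-terminus of MECP2. The last 2 were ChIP-seq libraries for H3 and for H3K9me3, the trimethylated lysine of histone H3 that marks heterochromatin. The CUT&RUN conditions varied in the amount of MECP2 antibody (raised 20-fold in a control experiment, per the labels' protocol), in the nuclease digestion time (30 minutes or 2 hours) and in how the DNA was recovered. The labels attach the 20-fold increase to the H3 library, whereas the only title with the number 10 in place of 0.5 is that of a MECP2 library, so which library it describes is uncertain. A processed file was used here for 1 library, the H3K9me3 ChIP-seq. The other 11 libraries were not analysed here, so no comparison between antibodies, digestion times or assays was made.

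The authors' deposited file is a list of H3K9me3 regions with 3 columns (chromosome, start and end) on mm10. Its name says that the regions were set against H3. The authors' list holds no score, fold, p-value or read count per region, so the depth behind the regions is unknown. Regions cannot be ranked by strength, and no counting interval was computed for any single region. Per the submitters' processing notes, the tools named for the series were cutadapt 2.5, Bowtie2 2.4.2, SAMtools 1.6, HOMER, deepTools 3.5.0 and SICER, and the build was mm10. The notes as used here do not say which tool made which file. The caller's settings, its threshold and any pooling of animals are not given in the sources used here. All but 60 of the 27180 regions are 1 bp shorter than a multiple of 500 bp. The offset of their starts from a 500 bp grid changes along every chromosome, which bears on how the coordinates were made and is taken up in the closing observations.

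Regions were read as half-open intervals, and coordinates are printed counting from 1. No regions overlapped one another. Chromosome lengths of mm10 came from GenomeInfoDb 1.38.1. Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly behind mm10. It holds 49997 genes, 49943 of them on chromosomes 1 to 19, X and Y and 21887 of those protein-coding. No region and no gene ended beyond its mm10 chromosome. The table gives no strand and no exons, and no genome sequence was used here, so promoters, exons, base composition and repeats were not analysed. A gene counted as having a region when at least 1 bp of its annotated body was covered. Overlapping gene models were each counted.

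Because there was 1 region list and no replicate, no p-value is given. Observed values are set beside 3 kinds of reference instead, each describing this list only. The regions were placed at random without overlap on their own chromosomes, 1000 times. The list was shifted by a random distance around each chromosome, 1000 times, which keeps the lengths and spacing of the regions. In addition, each gene list was set beside the circular shifts and compared with 10000 random lists of as many protein-coding genes, matched on gene length in 20 bins. A list is called higher or lower where at most 2.5% of the random lists had as many, or as few, genes with a region. Expected percentages are the means of the length-matched lists unless the shifts are named. The pool of random lists includes the listed genes themselves.

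The 26 gene lists, the tests of the comparisons, most alternative settings and the rule for naming genes were fixed before the data were examined. Tests of explanations in the closing observations were in part chosen later, as stated there. About 1.3 of 26 lists would fall outside the central 95% by chance if list members were independent. Members of 1 family are often neighbours, so the number called by chance may be higher. Pattern lists took protein-coding symbols of a family. The other lists were written by symbol and matched through symbols or synonyms. All written symbols were matched, and 2 housekeeping symbols named 1 gene. The genes named are the 25 protein-coding genes with the most covered bases among those at least 50% covered, up to 4 genes per list by covered bases, and Mecp2, Peg3, Snrpn, H19, Trim28 and Setdb1. The regions named are the 10 longest and the 5 windows of 5 Mb with the most covered bases. Alternatives kept only regions at least as long as the median, merged regions within 5 kb, required 50% of a gene body, matched lists on chromosome as well, left out a chromosome, or changed the window or the shift.

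The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and were tested on simulated data. Covered bases equalled a base-by-base count for all 1374 genes of chromosome 19. All 200 genes planted under simulated regions were recovered as fully covered. Of 200 random lists on randomly placed regions, 6 were called, a check that does not cover lists of neighbouring genes.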

Results

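The series asks which regulatory sequences the methyl-CpG-binding protein MeCP2 contacts in the mouse cortex. Its 12 libraries each stand alone in their group, and the regions analysed come from ChIP-seq of H3K9me3, a mark of heterochromatin, set against H3 in the same tissue. The H3K9me3 list held 27180 regions that together covered 266 Mb, or 9.75% of the mm10 chromosomes and 10.7% of the autosomes. The median region was 7.00 kb long, with quartiles at 5.00 and 10.5 kb, and lengths ran from 0.499 to 321 kb. Regions of at least 50 kb numbered 429 and held 13.9% of the covered bases, and 107 regions reached 100 kb. These values describe 1 region list with no replicate, and the read depth behind it is unknown.

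The question of where along the genome H3K9me3 exceeded H3 was addressed first by chromosome. Chromosome 7 had the highest coverage, 19% of its length, which is 1.95 times its share by length. Chromosome 17 followed with 16.2% (1.66 times) and chromosome 13 with 13.4% (1.37 times). The 19 autosomes ranged from 7.31% on chromosome 15 to 19% on chromosome 7, with a median of 9.77%. Chromosome X was covered over 1.5% of its length by 277 regions, 0.154 times its share. Its density was 1.62 regions per Mb, against 9.23 to 13.1 per Mb on the autosomes. Its regions were not shorter, with a median of 7.50 kb against 6.5 to 9.0 kb for the autosomes. Chromosome Y held 35 regions, all before 4.24 Mb, which is the first 4.62% of the chromosome. Whether reads could be mapped to the rest was not assessed here, so the rest cannot be said to lack the mark. Counted as regions per Mb, chromosomes 7 and 17 stood at 1.17 and 1.24 times the value for all chromosomes, which include the sparse X and Y. By that count chromosome 13 was higher than both (1.31), and chromosomes 1 (1.21) and 3 (1.20) were higher than chromosome 7. Chromosome 7 was thus not set apart from other autosomes by its number of regions.

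**Figure D1:**
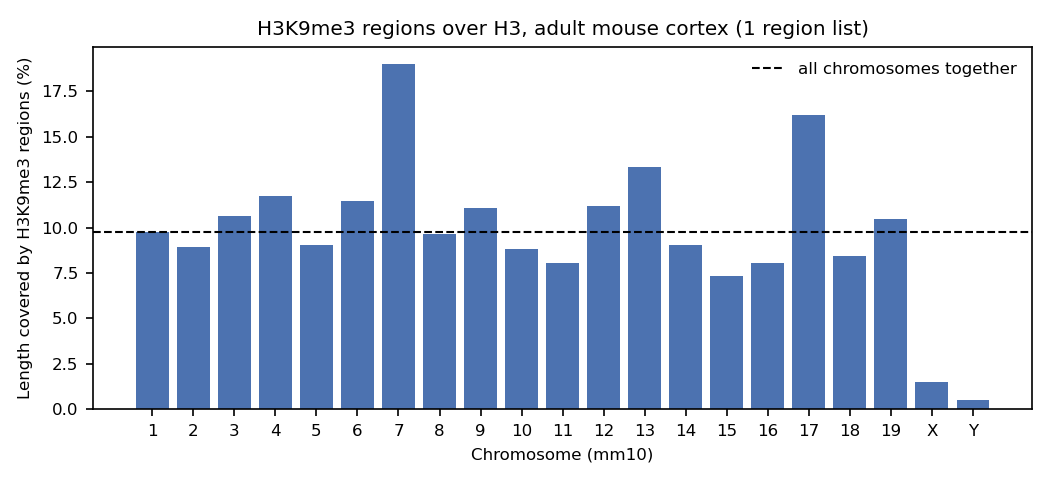
Bars show the percentage of each mm10 chromosome's length covered by H3K9me3 regions, with a dashed line at the value for all chromosomes together (9.75%). Chromosomes 7 (19%) and 17 (16.2%) stand highest, and chromosomes X (1.5%) and Y (0.490%) lowest.

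Regions lay close together. The median gap to the next region was 27.5 kb, against 55.6 to 58.1 kb in 1000 random placements. Gaps of 5 kb or less made up 15.4% of all gaps, against 5.58% to 6.39% in the placements. The 5 windows of 5 Mb with the most covered bases held 5.53% of all covered bases, against 2.06% to 2.53% in the placements. The densest window, chromosome 7 from 10000001 to 15000000, was covered over 70.8% of its length. Among its 72 protein-coding genes were 25 Vmn1r and 7 Vmn2r genes, which encode vomeronasal pheromone receptors, and 7 Zfp genes. Chromosome 6 from 130000001 to 135000000 was covered over 60.6% and contains 24 taste receptor genes and 9 Klr genes, a family of natural killer cell lectin receptors. The remaining windows lie on chromosome 17. That from 35000001 to 40000000 (56.8% covered) contains 46 olfactory receptor and 24 H2 genes, the latter of the major histocompatibility complex. The window from 20000001 to 25000000 (53.2%) contains 24 Zfp and 15 Vmn2r genes, and that from 15000001 to 20000000 (52.3%) contains 15 Vmn2r genes.

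The longest single region, of 321 kb on chromosome 4 (113029896 to 113351394), overlapped Skint6, of the Skint family of immunoglobulin-like proteins. Genes named for these regions overlapped them and need not lie wholly within them. A region of 207 kb (112814896 to 113021894) overlapped Skint6 as well, and one of 227 kb (112107896 to 112335394) overlapped Skint3 and Skint4. On chromosome 17, a region of 297 kb (19293037 to 19590535) overlapped Vmn2r99, Vmn2r100 and Vmn2r101. One of 286 kb on chromosome 5 (109248482 to 109534480) overlapped Vmn2r15, Vmn2r16, Vmn2r17 and Gm50598. Mug1, which encodes murinoglobulin, a plasma protease inhibitor, was overlapped by a region of 285 kb on chromosome 6 (121703983 to 121989481). Regions of 267 kb (61527141 to 61794639) and 218 kb (61112640 to 61331138) on chromosome 13 overlapped cathepsin genes, among them Cts3, Ctsm, Cts6, Cts8 and Ctsr. A region of 231 kb on chromosome 4 (144340098 to 144571596) overlapped Aadacl3 and Pramel13 with 5 other genes. One of 218 kb on chromosome 7 (10563152 to 10781650) overlapped Nlrp4b, Vmn1r69, Vmn1r70 and Vmn1r71.

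Most of the covered sequence lay outside genes. Bodies of protein-coding genes held 16.6% of the covered bases, against 35.8% to 42.2% when the list was shifted around the chromosomes, or 0.420 times the mean of the shifts. With all annotated genes the share was 27.3%, against 44.9% to 51.4%. A region overlapped 4034 of 21887 protein-coding genes (18.4%), against 28.2% to 31.7% in the shifts. At least 50% of the body was covered in 1637 genes (7.48%). Pseudogenes were overlapped in 21.2% of 9944 cases, lncRNA genes in 16.5% of 12727 and miRNA genes in 2.20% of 1228. At least 50% of the body was covered in 18.6%, 4.46% and 2.20% of them. These classes were not matched on gene length or set beside the shifts, so their shares cannot be compared directly.

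Among the 25 protein-coding genes with the most covered bases and at least 50% of the body covered, 10 were models of the clustered protocadherin locus. They comprise Pcdhga1 (116 kb covered), Pcdhga2 (109 kb), Pcdhga3 (104 kb), Pcdhgb1 (97.6 kb), Pcdhga4 (92.6 kb), Pcdhgb2 (88.0 kb) and Pcdhga5 (83.5 kb). These 7 models end within 3 bp of each other and lie under 1 shared region, so their values are not independent. The others, Gm37013 (606 kb), Gm38666 (591 kb) and Gm38667 (585 kb), are long models over the same locus. Outside it, Skint5 was covered over 95.3% of its 522 kb, Skint6 over 97.6% of 482 kb and Skint4 over 96.4% of 96.1 kb. Cyp2c39, a cytochrome P450 gene, was covered over 83.3%, Muc16, a cell-surface mucin, over 93.6%, and Catsperb, a sperm calcium channel subunit, over 74.9%. Adgre4, an adhesion receptor of myeloid cells, was covered over 89.9%, Slc22a27, an organic anion transporter, over 84.7% and Cntnap3, a contactin-associated protein, over 59.5%. Pax3, a neural crest and muscle transcription factor, was covered over 91.0% of its 95.9 kb. The other members of the 25 were Zfp978 (54.7%), Gm38510 (87.0%), Gm7247 (55%), Gm272 (88.2%) and Gm12880 (98.1%).

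Of the 26 gene lists, 9 had a region more often and 3 less often than the central 95% of length-matched random lists. All 9 of the former also lay above the central 95% of the circular shifts. Each list was scored over its annotated members, and members of 1 family are often neighbours under a shared region.

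Zfp genes, which encode zinc-finger proteins that often carry a KRAB repressor domain, had a region in 190 of 394 cases (48.2%, against 14.9% expected and a central 95% of 11.7% to 18.3%). Against the circular shifts, which had a mean of 31.0% and a central 95% of 23.9% to 38.6%, the excess was smaller, at 1.55 times in place of 3.24. At least 50% of the body was covered in 95 of them. Zfp978 (146 kb covered) and Zfp982 (73.0 kb, its whole body) lie on chromosome 4, and Zfp936 (70.9 kb, 91.0%) on chromosome 7. Zfp993 had 60.7 kb covered, 12.7% of its annotated body.

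Chemosensory receptor families were covered over much of their membership. Vomeronasal receptor genes had a region in 194 of 353 cases (55%, expected 20.2%), among them Vmn2r60 (67.3 kb covered), Vmn2r59 (47.2 kb), Vmn2r80 (46.1 kb) and Vmn2r81 (43.8 kb). Olfactory receptor genes had one in 503 of 1106 cases (45.5%, expected 25.0%), led by Olfr183 (35.4 kb), Olfr91 (32.4 kb), Olfr687 (21.5 kb) and Olfr872 (20.8 kb). Bitter taste receptor genes of the Tas2r family had one in 24 of 35 cases (68.6%, expected 26.0%). Tas2r102, Tas2r107, Tas2r123 and Tas2r110 each lay wholly within a region on chromosome 6. In the shifts, means were 23.4% for vomeronasal, 13.8% for olfactory and 12.4% for taste receptor genes. Without chromosome 6, neither of the other 2 Tas2r genes had a region.

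Clustered protocadherin genes, which encode cell-surface identity proteins of neurons, had a region in 52 of 57 cases (91.2%, expected 26.9%). The Pcdhb genes (chromosome 18, 37264998 to 37521419) were each at least 50% covered, 22 of 22, and 94.3% of their span was covered. Of the Pcdhg span (37661775 to 37841873), 64.4% was covered, and of the Pcdha span (36930285 to 37188897) 40.0%, with none of the 14 Pcdha genes at least 50% covered. Pcdha1 had 104 kb covered. In the circular shifts, 44.8% of the protocadherin genes had a region on average.

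**Figure D2:**
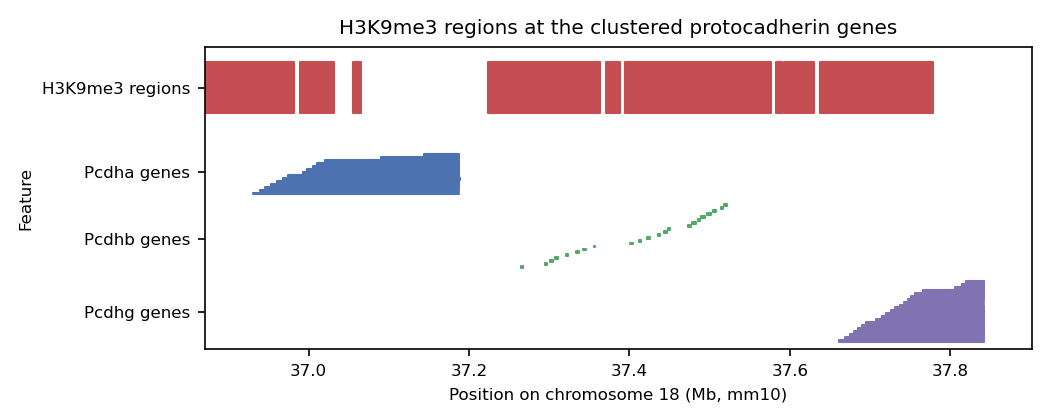
H3K9me3 regions (red) and the gene bodies of the Pcdha, Pcdhb and Pcdhg families (1 line per gene) are drawn to scale by position on chromosome 18 in Mb. Regions cover 94.3% of the Pcdhb span, 64.4% of the Pcdhg span and 40.0% of the Pcdha span.

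Drug- and steroid-metabolizing cytochrome P450 genes of the Cyp2 and Cyp3 families had a region in 41 of 54 cases (75.9%, expected 14.7%), led by Cyp2c39 (185 kb), Cyp2c38 (58.0 kb), Cyp2c66 (53.7 kb) and Cyp2j8 (45.9 kb). The mean of the shifts for these genes was 30.7%, which lowers the excess from 5.18 to 2.47 times. Defensin genes, which encode antimicrobial peptides, had one in 33 of 70 cases (47.1%, expected 19.3%), with Defb14 (23.8 kb), Defb1 (9.13 kb), Defb39 (7.10 kb) and Defb50 (5.27 kb) the most covered. The mean of the shifts was 12.4% for defensin genes. The defensin result rested on chromosome 8, without which 1 of 18 genes had a region (5.56%, expected 13.7%).

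Hox genes, the transcription factors of the body axis, had a region in 32 of 39 cases (82.1%, expected 12.1%), and 25 of them were at least 50% covered. Regions covered 85.9% of the Hoxa span (chromosome 6, 52155367 to 52260880), 85.0% of the Hoxd span (chromosome 2, 74668225 to 74765142), 66.4% of the Hoxb span (chromosome 11, 96194316 to 96368254) and 60.5% of the Hoxc span (chromosome 15, 102921131 to 103036856). Hoxa3 was covered over 95.5%, Hoxd3 over 90.5%, Hoxb3 over 73.1% and Hoxd10 over its whole body. The list of other developmental transcription factors had a region in 26 of 42 cases (61.9%, expected 16.2%). In the shifts the means were 15.0% for the Hox and 30.6% for the developmental list, which lowers the excess of the latter from 3.83 to 2.03 times. Pax3 led with 87.2 kb, followed by Tbx15 (59.2 kb), Gata4 (35.0 kb) and Tbx5 (34.0 kb).

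**Figure D3:**
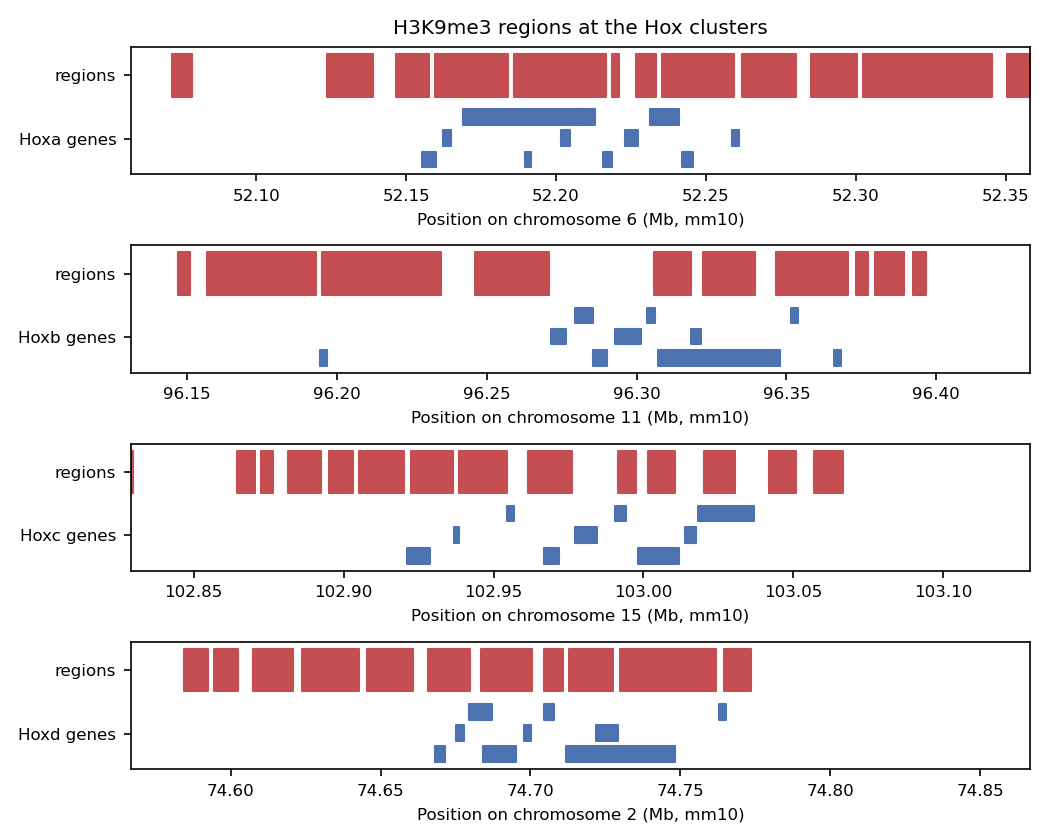
H3K9me3 regions (red) and Hox gene bodies (blue) are drawn to scale by position in Mb in a 0.3 Mb window around each of the 4 clusters. Regions cover 85.9% of the Hoxa, 66.4% of the Hoxb, 60.5% of the Hoxc and 85.0% of the Hoxd span.

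Ribosomal protein, histone and keratin-associated protein genes had a region less often than length-matched lists. Ribosomal protein genes had a region in 1 of 81 cases (1.23%, expected 13.5%), the exception in the list being Rpl39l, and also lay below the central 95% of the circular shifts. A later grouping by symbol stem, which takes in Rpl genes outside this list, had 2 of 53 with a region. None of the 67 histone genes had one (expected 22.5%), and keratin-associated protein genes, expressed in hair, had one in 3 of 52 cases (5.77%, expected 25.0%), namely Krtap27-1, Krtap12-1 and Krtap19-5. The histone and keratin-associated results lay within the central 95% of the circular shifts, where on average 14.4% and 10.2% had a region. Length-matched lists were drawn from a pool that includes the 1106 olfactory receptor genes, 45.5% of them with a region. How far such families raised the expected shares was not tested. The keratin-associated call also ended when lists were matched on chromosome as well (expected 14.6%) and without chromosome 11 (10.3%), and the histone call without chromosome 13, where 14 genes were left. None of the 26 housekeeping genes had a region (expected 12.4%). That list lay within the central 95% of the length-matched lists, which began at 0% so that no lower call was possible. It lay below the central 95% when lists were matched on chromosome as well (expected 14.4%, central 95% 3.85% to 26.9%). The housekeeping list also lay below the central 95% of the shifts, as did the genes of H3K9 methylation and its readers (1 of 22, with 4.00 kb covered in Atf7ip) and the non-neural tissue genes (1 of 25, with 113 kb covered in Ttn, the gene of the muscle protein titin). The H3K9 methylation and non-neural tissue lists lay within the central 95% of length-matched lists. Protein-coding genes as a whole were also below the shifts (18.4%, against 28.2% to 31.7%), so this is not in itself particular to these lists.

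Marker genes of cortical cell types were within the central 95% of length-matched lists. For the short astrocyte, oligodendrocyte, microglia, endothelial, activity-regulated and inhibitory neuron lists that range began at 0%. A lower call was therefore not possible for them, and their place within it does not show an ordinary share. No region overlapped any of 9 astrocyte, 11 oligodendrocyte or 11 activity-regulated genes. Among microglia genes 1 of 10 had a region (Itgam, 3.5 kb covered), and among endothelial genes 2 of 7 (Flt1, 17.5 kb, and Tek, 15.0 kb). The endothelial share of 28.6% lay above the 24.9% of length-matched lists and below the mean of the shifts, 42.5%. Inhibitory neuron genes had one in 5 of 14 cases (35.7%, expected 18.6%), against a mean of 30.7% in the shifts, which lowers the excess from 1.92 to 1.16 times. Without chromosome 2 the share was 25%, against 22.2% expected. Gad2, which encodes a GABA-synthesizing enzyme, was covered over 52.7% and Lhx6, an interneuron transcription factor, over 58.2%. In the long genes Adarb2 and Reln, 7.33% and 5.54% were covered, and 2.38% and 1.63% by regions at least as long as the median. Glutamatergic neuron genes had a region in 4 of 18 cases (22.2%, expected 30.2%), and in the shifts 50.1% did on average, with a central 95% of 33.3% to 66.7%. Slc17a6, a vesicular glutamate transporter, was covered over 53.3% and Tbr1, a cortical transcription factor, over 63.7%, whereas 2.08% of Cux2 and 3.2% of Bcl11b was covered.

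**Figure D4:**
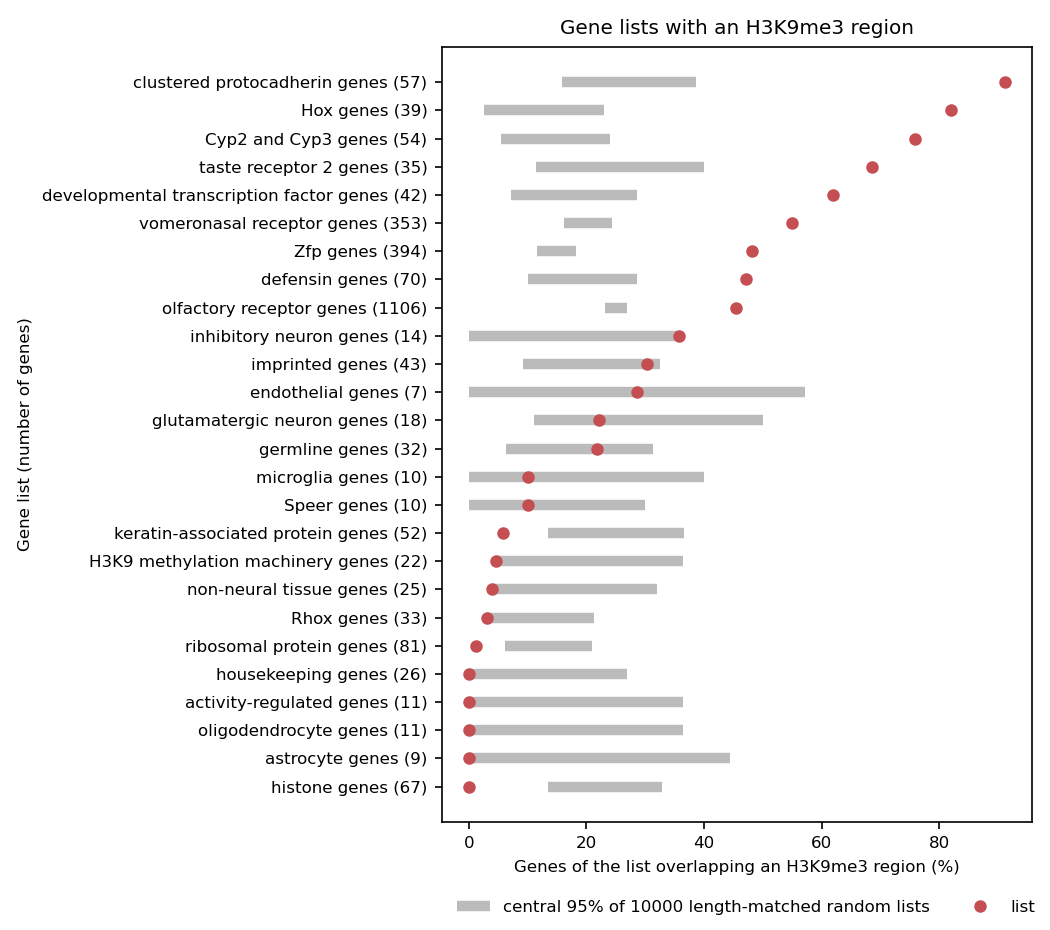
Points show the percentage of genes in each of the 26 lists that overlap an H3K9me3 region, with list sizes in brackets, and grey bars the central 95% of 10000 length-matched random lists. The 9 lists from olfactory receptors (45.5%) to clustered protocadherins (91.2%) lie right of their bars, and the keratin-associated, ribosomal protein and histone lists lie left of theirs.

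Imprinted genes had a region in 13 of 43 cases (30.2%), above the 19.7% expected from length-matched lists and below the 36.2% expected from the shifts, and within the central 95% of both. Of the 13, 8 lie on chromosome 7, without which 5 of 27 had a region (18.5%, expected 19.2%). Snrpn (chromosome 7, 59982495 to 60450177) was covered by 15 regions over 42.8% of its long annotated body. Zdbf2 was covered over 55.2%, Kcnq1ot1 over 30.0% and Grb10 over 19.2% (10.8% by regions at least as long as the median). No region overlapped the bodies of Peg3 or H19. Germline genes had a region in 7 of 32 cases (21.9%), above the 17% expected from length-matched lists and below the 29.1% expected from the shifts, and within the central 95% of both. They include Stk31 (35.5 kb), Sycp1 (23 kb), Tdrd9 (7.56 kb) and Mov10l1 (5.00 kb), and no member was 50% covered. With regions at least as long as the median, 3 of 32 germline genes had one (9.38%, expected 10.4%). Rhox genes, a homeobox cluster on chromosome X, had a region in 1 of 33 cases (Rhox13, 82.0% covered), and Speer genes in 1 of 10 (Speer2, 34.6% covered). The Rhox share of 3.03% lay below the 10.6% of length-matched lists and above the 2.62% of the shifts, and the Speer share of 10% near 9.95% and below 14.0%. Mecp2 on chromosome X (74026592 to 74085690), and Trim28 and Setdb1, which act in setting H3K9me3, had no region in their bodies.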

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

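The circular shifts within the span of regions, the lists without X and Y and the overlapping members counted once were chosen after seeing the data, and the other alternatives before. The list holds no score, so the planned stricter thresholds were not run. Promoter windows, exons, base composition and shifts confined to sequenced bases were not run either, for want of strand, exons and a genome sequence. No paired analysis was possible because each group has 1 library. Of the alternatives to the main values of each comparison, 121 kept a count or length within 1.5 times, a share within its 95% interval, or a list or clustering value on the same side of its reference range. Another 12 went beyond that, 7 ended a call and 3 turned the direction. The 95% interval of genome and chromosome shares was binomial on the number of regions. It counted clustered regions of 1 list as independent, so it is a yardstick and no measure of spread between libraries. Keeping regions at least as long as the median left 14263 regions over 7.62% of the genome, with coverage relative to length of 2.25 on chromosome 7 and 1.82 on chromosome 17. Merging regions within 5 kb gave 10.2% of the genome and 251 regions of 100 kb or more. Counted as regions per Mb, the values were 1.17 on chromosome 7 and 1.24 on chromosome 17. Measured against the span from its first to its last region, chromosome Y turned from below to above its share (1.25), because that span is a small part of the chromosome. Requiring 50% of the body left 7.48% of protein-coding genes. Without the chromosome with most members, the defensin and taste receptor lists turned below expectation, at 5.56% and 0%, with 18 and 2 genes left, and the protocadherin and Rhox lists had no genes left. The histone list (0%) lost its lower call without chromosome 13, where 14 genes were left, and in both kinds of circular shift. The keratin-associated list lost its lower call without chromosome 11 (10.3%), when lists were also matched on chromosome (5.77%) and in both kinds of shift (5.77%). Lower lists numbered 5 in both kinds of shift and 1 without the chromosome with most members. The cause of these changes was not tested beyond the smaller number of genes. None of the 9 higher calls was lost with either kind of shift, with long regions, with 50% of the body, with lists matched on chromosome, without X and Y, or with overlapping members counted once. The imprinted list was higher with regions at least as long as the median (25.6%) and with overlapping members counted once (35.1%), but below expectation without chromosome 7 (18.5%) and in both kinds of shift, and the inhibitory neuron list with regions at least as long as the median (35.7%). The housekeeping list (0%) was lower when lists were also matched on chromosome and in both kinds of shift, and the glutamatergic neuron (22.2%), H3K9 methylation (4.55%) and non-neural tissue (4%) lists were lower in both kinds of shift. Protein-coding genes as a whole (18.4%) also had a region less often than in both kinds of shift. Of 87 named genes, 75 kept their covered percentage within 1.5 times when only regions at least as long as the median were kept. Among the other 12, Adarb2, Reln and Grb10 kept a smaller part, and Atf7ip, Itgam, Flt1, Cux2, Bcl11b, Mov10l1, Speer2, Krtap12-1 and Krtap19-5 had no region left. The direction of the germline, endothelial, microglia, Speer, Rhox and glutamatergic lists against expectation turned under at least 1 setting. Read depth and the calling threshold are unknown, so a gene without a region cannot be said to lack the mark.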

Other observations

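The gene families described first were chosen after their values were seen, as were the tests below on reversed blocks, silent genes and H3K27me3; the other tests were chosen before. Antigen receptor segments differed by locus. Ighv segments of the immunoglobulin heavy chain on chromosome 12 had a region in 181 of 183 cases, 98.9%. Igkv segments of the kappa chain on chromosome 6 had one in 51 of 162 cases (31.5%), and Trav segments of the T cell receptor on chromosome 14 in 14 of 130 (10.8%). None of 35 Trbv segments had one. V-segment pseudogenes had a region in 60.1% of 153 cases and other V segments in 39.8% of 394.

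Grouping genes by symbol stem gave 271 stems of at least 10 protein-coding genes. In 180 of them no gene was at least 50% covered, and in 16 at least 50% of the genes were. The latter include Skint (11 of 11), Pate (13 of 14), Esp (13 of 15), which encodes exocrine-gland pheromone peptides, Psg (11 of 13), pregnancy-specific glycoproteins of the placenta, Klra (10 of 13), natural killer cell receptors, and Nlrp (13 of 18). Mup genes, which encode major urinary proteins, were at least 50% covered in 6 of 22 cases and Ugt genes, which conjugate drugs and hormones, in 7 of 22.

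The offset of regions from a 500 bp grid did not step between neighbours in 98.9% of 27159 neighbouring pairs and stepped to another value in the rest, and 60 regions had lengths off the grid. All 21 chromosomes had a change of offset. In 5 runs the deposited order ran backwards along the chromosome, the longest being 53 regions on chromosome 10 between 3.1 and 7.35 Mb, and all 5 of these reversed blocks ended at a change of offset, which suggests that regions were called on another build and then moved to mm10. Of the tests chosen before, that on off-grid regions left such a move open, with 28.1% of 57 joining the offsets on either side. The other found 8% of out-of-order regions at a change of offset. By the bound set before, this went against blocks being ordered differently in another build. That bound was later judged wrong, because a reversed block changes offset only at its edges. The test on reversed blocks was chosen after the values were seen, so such a move stays open. No biological explanation was tested for this pattern.

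Chromosome X was covered over 0.740% of its median 5 Mb window, against 7.80% for autosomal windows. Loss of parts of X in a change of build is argued against, since 2 of 35 X windows reached the autosomal lower quartile (5.30%) and the deficit runs along the chromosome. A lack of dense gene-family domains is argued against as the whole cause, because the median X window stood at the 1.39 percentile of the 503 autosomal windows. Fewer reads on X, for example from male animals, may account for the deficit and cannot be told apart from a lower level of the mark, as long regions were depleted about as much as short ones (ratio of ratios 0.921) and the list gives no read counts. The labels used here do not give the sex of the animals. The 35 regions on chromosome Y need reads assigned to Y, so male tissue may have been used, but the list does not show how much. Within the span from first to last region, Y had 1.25 times its share of covered bases and X 0.149 times. Both are single in male cells, so copy number alone would not be expected to set them this far apart. The Y span was set by its own 35 regions and is a small part of Y, so this does not settle the cause. No biological explanation of the deficit on X was tested.

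Hox and developmental transcription factor genes, known mainly as targets of Polycomb and H3K27me3, often had a region. Of biological explanations, only silence in adult cortex was examined, and only indirectly through gene lists. Gene length alone is argued against, since 100% of length-matched random lists had fewer genes with a region than either list. Silence in adult cortex, which was not measured here, is argued against only as the whole cause. Of non-neural tissue genes, 1 of 25 had a region (upper exact 95% bound 20.4%), below the lower bound for the developmental list (45.6%). Families used mainly outside the cortex differed among themselves. Cyp2 and Cyp3 (75.9%), taste receptor (68.6%), vomeronasal (55%) and defensin (47.1%) genes often had a region. Keratin-associated (5.77%), Rhox (3.03%), Speer (10%) and germline (21.9%) genes had one less often. The Rhox genes lie on X, where regions are few, and 3.38% was expected with lists matched on chromosome as well. Speer and germline genes were near or above their length-matched expectations (9.95% and 17%). The taste receptor and defensin values each rested on 1 chromosome. A part played by silence therefore stays open. The 26 covered developmental genes lay in 21 loci more than 1 Mb apart (80.8%), counted from gene positions, and so were not under a few shared regions. The listed genes were spread over many chromosomes to begin with, so this share was largely set by the list. Binding of the antibody to H3K27me3 may account for the regions at Hox genes (82.1% with a region), and cannot be told apart from H3K9me3 at these genes, because no H3K27me3 profile was used here.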
